A study of Mus musculus with 16 samples.

How the data were processed

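Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adaptors into open DNA. The material was mouse embryonic stem cells with the genotype label FOXD3-iKO, grown in L2i medium. Per the labels, FOXD3 depletion was induced with tamoxifen (4HT), ethanol (EtOH) was the control, and the treatment time was 24 h. Cells were sorted by DNA content after DAPI labelling into fractions named G1, ES, LS and G2. The names ES and LS are used as the labels give them.

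The authors deposited a table of accessible regions and a table of windows of 5000 bp around transcription start sites (TSSs). Both hold a coverage signal in 8 columns, 1 for each treatment and fraction, and no column carries a replicate number. The 2 libraries of each group, 16 in all, were therefore taken as pooled by the authors, and every value below is a pooled value with no SD. Per the submitters' processing notes, the build was mm10 and the tools named were featureCounts and DESeq2, with no role or version. The aligner, the coverage program and the replicate handling were not given in the sources used here.

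In each column of deposited signal the smallest value was shared by many intervals, intervals without a read had no value, and none lay below that smallest value. The signal was read as coverage in CPM (counts scaled to library size), averaged over the bases that hold a read, and the smallest value as the worth of 1 read. The implied depth was 6.78, 9.75, 11.1 and 8.87 M reads for 4HT in G1, ES, LS and G2, and 9.96, 8.38, 8.17 and 11.2 M reads for EtOH. In this unit a weak interval cannot fall below the 1-read value, which is higher in a shallower column. Differences of weak intervals therefore follow depth, and losses are understated. Between 19.9% and 32.8% of the regions had no read in a given column, and a further 29.6% to 34.5% stood at 1 read.

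A level is given below as a multiple of the 1-read value, averaged over the 8 columns. Intervals were tested if they had a read in every column and a mean multiple of at least 2 (11010 of 127646 regions) or 1.3 (15323 of 38053 distinct windows). This filter leaves out intervals that lost all reads in any column. The signal was transformed as log2(signal + 0.1), so that folds of low intervals are understated, and centred across columns along the level with cyclic loess in limma 3.58.1 under R 4.3.3. Without centring, the median 4HT minus EtOH difference of the windows lay between -0.17 in LS and 0.25 in G1.

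A limma model with terms for treatment and fraction was fitted to the 8 columns, with 3 residual degrees of freedom, an intensity trend and robust moderation. Benjamini-Hochberg adjusted p at 0.05 was the threshold. The 4 fractions served as repeats of the treatment contrast and the 2 treatments as repeats of each fraction contrast. The p-values thus measure the spread among pooled columns, not among cultures. Contrasts of treatment within 1 fraction, and the interaction of treatment and fraction, could not be tested, and only their values are given. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Intervals of correlations across intervals or bins are 95% limits from 1000 bootstrap draws of 10 Mb blocks, and neither intervals nor genes are independent replicates.

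Windows were given gene symbols from a RefSeq table of GRCm38.p6, the assembly named mm10, when a TSS lay within 500 bp of the window's reference point. That point was offset by 150 bp from the window centre. A name was found for 27165 windows, which cover 28777 genes, 17851 of the 21887 protein-coding genes among them. A region within 1000 bp of a TSS was called proximal.

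Before the data were examined, the groups, the 19 gene lists, the tests for 16 separate libraries, the rule for named genes and a first set of alternatives were fixed. Those alternatives were other pseudocounts, no filter, a signal minimum, other scalings, the removal of 1 Mb domain medians, and fits of the compared columns. That design took log2(signal + 0.5), a mean signal of at least 1 and the values as deposited. The additive model over pooled columns, the pseudocount used, the centring, the coverage minimum and the higher coverage minimum were chosen after seeing the data. The same holds for the correction for reads hidden by the average, the omission of single fractions, and fraction contrasts averaged over treatments. The fry test was not part of the design fixed before either. The naming rule took the largest called changes with the same sign in all fractions and a mean signal of at least 2, passed over predicted symbols, and took the 2 largest members of a list with no called member. Its conditions on replicates could not be applied, and called intervals that it does not cover were named after their values were seen. Some list members that the rule names are not reported here.

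The pipeline was tested on simulated data with 200 changed intervals per table for the treatment contrast. Among 15323 windows, rises of 0.5, 1 and 2 on the log2 scale were recovered in 91.2%, 100% and 100% of cases. Falls of the same sizes were recovered in 84.8%, 78.8% and 78.8%, with median estimates of -0.33, -0.37 and -0.39. Among 11010 regions the shares were 11.8%, 88.2% and 100% for rises and 0%, 60.6% and 63.6% for falls. False calls numbered 7 of 185 in windows and 6 of 114 in regions. The noise was drawn independently for each interval, with the spread of the fit itself. These shares thus hold for data that meet the assumptions of the model, and do not test those assumptions. With 200 changed intervals the adjusted threshold is also easier to pass than where few intervals change. Motif tests were not run, because no genome sequence was used here.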

Results

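The series asked how chromatin accessibility of mouse embryonic stem cells changes after depletion of FOXD3, a forkhead transcription factor of pluripotent cells and the neural crest, and whether the change depends on cell cycle phase. Each of the 8 groups (4HT or EtOH in G1, ES, LS or G2) comprised 2 libraries and is represented by 1 pooled column, with a depth of 6.78 to 11.2 M reads.

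Among the gene lists, promoter accessibility was highest at genes of DNA replication. The TSS windows of the S phase and replication list had a median level of 2.10 times the 1-read value, against 1.27 for all 25570 named windows with a read in every column. Within it, Gins2, a subunit of the replicative helicase complex, stood at 4.398 and Slbp, which binds histone mRNA, at 2.89. The median of the p53 and DNA damage response list was 1.78 (Rrm2b 2.65, Sesn1 2.55), that of G2 and mitosis 1.72 (Ckap2 2.40, Ccnf 2.33) and that of ribosomal proteins 1.70 (Rps19 2.68). Naive pluripotency genes had a median of 1.61, led by Klf2 at 2.73, Pou5f1 at 2.65 and Zfp42 at 2.58.

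Genes of differentiated lineages lay near the median of all windows. Neuroectoderm had a median of 1.32 (Tubb3 1.67), primitive endoderm 1.296 (Lamc1 2.05), mesendoderm 1.34 (Tbx6 1.86), neural crest 1.26 (Erbb3 1.66) and fibroblast markers, a list for another cell type, 1.28 (Fn1 1.65). Formative and primed pluripotency stood at 1.33 (Etv4 1.64) and Wnt targets at 1.34 (Znrf3 2.63). The two-cell-like list was the lowest at 1.15, although Duxf3, a gene of the Dux family that drives the two-cell programme, stood at 2.49. Chromatin repressors had a median of 1.54 (Mbd3 3.51, Trim28 3.20), Nodal, TGF-beta and BMP targets 1.53 (Smad7 and Nodal 2.42 each), histones 1.48 (H1f1 2.29), apoptosis regulators 1.47 (Apaf1 2.68), FGF and MAPK feedback 1.45 (Etv5 2.25) and trophectoderm 1.40 (Id2 1.77). Among 10000 random lists of the same size, the percentile was 100 for S phase, p53 and ribosomal proteins, 99.99 for naive pluripotency, 43.5 for neural crest and 0.56 for the two-cell-like list. The median of all windows and the random lists were taken from all named windows, which include genes that code for no protein. They are therefore no comparison with promoters of protein-coding genes alone. These percentiles describe the 8 columns and are no test between groups.

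**Figure D1:**
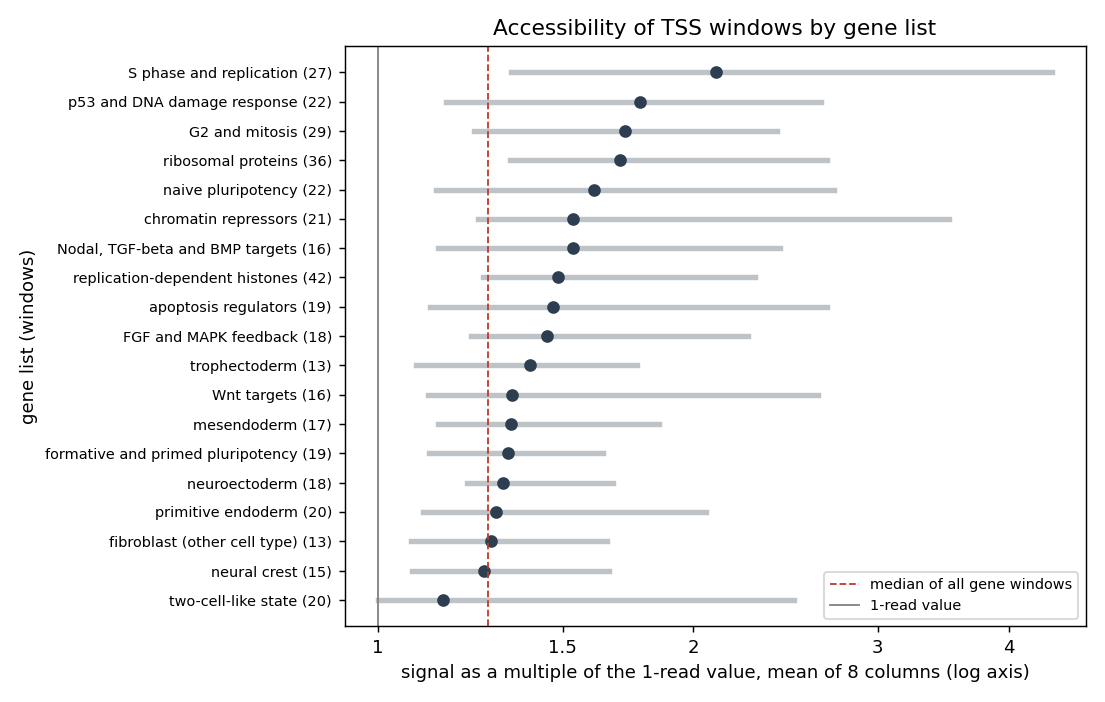
Signal of TSS windows as a multiple of the 1-read value, averaged over 8 columns (log axis), for each gene list, with the number of windows in parentheses. Points are medians and bars run from the lowest to the highest member; S phase and replication lies highest at 2.10 and the two-cell-like state lowest at 1.15, with the median of all gene windows at 1.27.

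Regions near promoters carried more signal than the rest. The 19232 proximal regions had a median level of 1.49 and 64.1% had a read in every column, whereas the 108414 other regions had a median of 0.942 and 24.5% had a read in every column. Proximal regions made up 15.1% of all regions and 49.2% of those tested. The share of regions with a read followed depth across the 8 columns (Pearson r 0.991, exact permutation p 0.000198; Spearman rho 0.952, p 0.00114; adjusted over 2 relations to the same values). Without the 2 columns farthest from the median depth, r was 0.989. The mean share with a read was 74.2% in 4HT and 75.6% in EtOH, a difference of -1.32 points (exact two-sided permutation p 0.875 over 16 swaps within fractions, with 0.125 the smallest possible).

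Foxd3 itself (chromosome 4, 99656299 to 99658671, mm10) had a mean level of 1.49 times the 1-read value at its TSS window (99653650 to 99658649), above the median of 1.27 for all named windows. The signal of that window was 0.243, 0.158, 0.141 and 0.169 in 4HT in G1, ES, LS and G2, and 0.153, 0.195, 0.155 and 0.110 in EtOH, or 1.23 to 1.65 times the 1-read value. Of the accessible regions over the gene, the one at 99657277 to 99657563 differed between 4HT and EtOH by log2 1.46, 0.25, 0.08 and -0.24 in G1, ES, LS and G2, and the one at 99657631 to 99658063 by 1.22, 0.48, 0.51 and 0.28, at 1 to 2.045 times the 1-read value. The labels do not say which part of the gene is removed, and an average over covered bases hides a loss, so these values do not check the depletion.

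Across the 4 fractions, few intervals passed the test between 4HT and EtOH cells. No accessible region passed the threshold in limma (smallest adjusted p 0.218), with 597 of 11010 at an unadjusted p under 0.05 against 550.5 by chance. Of 15323 TSS windows, 1 rose and 1 fell, with 809 at an unadjusted p under 0.05 against 766 by chance. The window that rose lies at chromosome 9, 3013005 to 3018004, overlaps no gene in the table, and was 1.64-fold higher in 4HT (log2 0.71, SE 0.12, adjusted p 0.00875, 4 of 4 fractions). The window that fell holds the predicted gene Gm21560 (chromosome 14, 6216943 to 6221942) and was 1.44-fold lower (log2 -0.53, SE 0.09, adjusted p 0.00875, 4 of 4 fractions). Its 4HT signal was the 1-read value in G1, LS and G2 (0.147, 0.0903 and 0.113), and its EtOH signal was so in LS (0.122). In LS, where both treatments stood at 1 read, the difference of -0.06 measures no loss. Neither of the 2 windows had a mean signal of 2, so both were named after their values were seen. Both calls depend on the setting. No window passed with a pseudocount of 2 (smallest adjusted p 0.0971), with no filter (0.166), as deposited without centring (0.0554), with 1 Mb domain medians removed (0.897) or without the G2 fraction (0.886). In these settings other than the pseudocount, which shrinks the scale, the chromosome 9 window stood at log2 0.71, 0.69, 0.58 and 0.55 and the Gm21560 window at -0.53, -0.50, -0.42 and -0.50. The Gm21560 window was also lost without the G1 fraction (-0.47, adjusted p 0.155) and without the ES fraction (-0.46, adjusted p 0.0646), and lay under the higher coverage minimum.

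The chromosome 9 window lies in the segment at the start of that chromosome, which is counted below among repeated loci. Its sequence was not examined. A gain in accessibility therefore cannot be told apart from a change in reads shared by repeats. The neighbours of this window had smaller values. A window that overlaps it, starting at 3014759, had a log2 difference of 0.45 (adjusted p 0.438), and the windows with the highest signal of that segment, starting at 3020898 and 3022768, had differences of 0.08 and -0.00.

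No pluripotency or lineage list passed the test for 4HT against EtOH. The 18 tested naive pluripotency windows had a median log2 difference of -0.04, with 6 above 0, and the largest values were -0.20 for Dppa5a and -0.14 for Tfcp2l1. Formative and primed genes had a median of 0.03 over 13 windows (Lef1 -0.15, Etv4 0.10). Neural crest genes, whose precursors depend on FOXD3, had a median of 0.00 over 6 windows (Ngfr 0.15, Msx1 -0.14). Medians for neuroectoderm were -0.00 (Sox21 -0.13, Irx3 0.08), for mesendoderm -0.00 (Tbx6 -0.14, Cdx1 0.12), for primitive endoderm -0.01 (Sparc 0.18, Col4a1 -0.12), for trophectoderm -0.04 (Gata2 0.16, Id2 -0.12), and for fibroblast markers 0.02 (Mmp2 -0.13, Col1a1 0.08).

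No signalling or cell cycle list passed either. FGF and MAPK feedback had a median of 0.04 (Il17rd -0.24, Dusp4 0.12), Nodal, TGF-beta and BMP targets -0.02 (the inhibitory Smads Smad7 0.25 and Smad6 0.16), Wnt targets -0.01 (Znrf3 0.26, Lef1 -0.15), chromatin repressors 0.01 (Ezh2, the Polycomb methyltransferase, -0.22 and Mbd3 -0.21), p53 response 0.01 (Sesn2 0.23, Zmat3 -0.15) and apoptosis regulators -0.02 (Apaf1 -0.16). S phase genes had a median of 0.00 (Cdc45 -0.21), mitotic genes -0.02 (Top2a 0.18, Plk1 -0.16), ribosomal proteins 0.01 (Rpl23 0.19, Rpl11 0.17) and two-cell-like genes 0.02 (Arg2 0.11, Tmem92 -0.09). The histone list had the smallest p (median -0.06 over 36 windows, 11 above 0, H1f2 -0.34 and H2bc4 -0.24, camera p 0.0162, adjusted p 0.307). None of the 19 lists passed with camera, with an estimated correlation (smallest adjusted p = 0.979) or with fry (smallest adjusted p = 0.954). No list member was called over all windows or adjusted over the list alone.

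**Figure D2:**
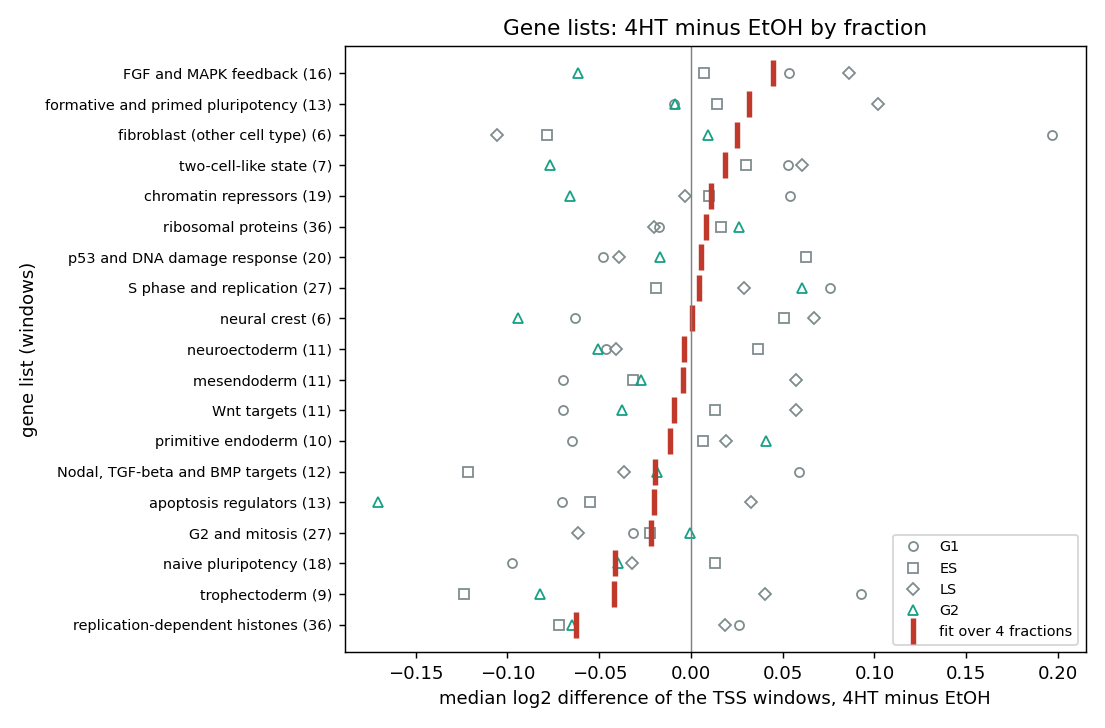
Median log2 difference of TSS windows between 4HT and EtOH for each gene list (number of windows in parentheses). Open symbols are the 4 fractions and red bars the fit over all of them; the fitted medians run from -0.06 for replication-dependent histones to 0.04 for FGF and MAPK feedback.

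Within single fractions, the genes with the widest differences are given as values. In G1 the TSS windows of Pik3r3, a regulatory subunit of PI3 kinase, and Zfp600 were higher in 4HT by log2 1.11 and 0.96, and those of Sec11c and Cenpo lower (-0.82 and -0.80). In ES, Rita1 stood at 0.79 and Bsdc1 at -0.91. In LS, the window shared by Zfp91 and Gm44505 stood at 0.82 and Fnta, a farnesyltransferase subunit, at -0.98, and the overlapping windows of the histone genes H2bc4 and H2ac6 at -0.92. In G2, Enox2 stood at 0.76 and Ifnz at -1.001. Over the 24 windows so ranked, the sign in the other fractions was the same in 39 of 72 cases (54.2%). These are values of single pairs of columns with no test.

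List medians within fractions were likewise spread around 0. Of 76 medians, 4 lay outside the central 95% of random lists matched on level, where 3.8 are expected by chance. They were Nodal, TGF-beta and BMP targets in ES (-0.12), apoptosis regulators in G2 (-0.17), histones in ES (-0.07) and fibroblast markers in G1 (0.20). Differences between 4HT and EtOH hardly correlated between fractions: Pearson r across regions ran from 0.0036 to 0.023 over the 6 pairs (mean 0.00925, 95% interval 0.000356 to 0.0184), and across windows from -0.019 to 0.023 (mean 0.00465, -0.00310 to 0.0127).

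**Figure D3:**
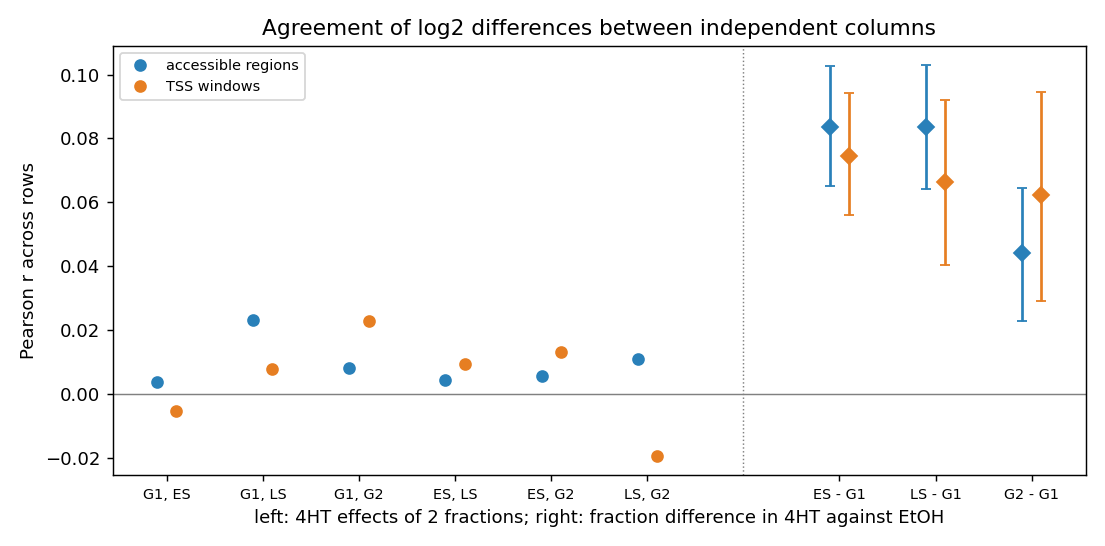
Pearson r across regions (blue) or TSS windows (orange). Left, 4HT minus EtOH differences of each pair of fractions, from -0.019 to 0.023; right, differences of a fraction from G1 in 4HT against the same difference in EtOH, from 0.0442 to 0.0837, with 95% bootstrap intervals as bars.

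A few loci rose steeply in G2 relative to G1, averaged over treatments. A window on chromosome 17 (39846478 to 39851477) that overlaps the ribosomal RNA pseudogene Rn18s-rs5 and the noncoding gene AY036118 was 5.87-fold higher (log2 2.55, SE 0.19, adjusted p 6.9e-13). A window at chromosome 13, 9832176 to 9837175, with no gene, was 4.50-fold higher (log2 2.17, SE 0.20), a window within Zc3h7a on chromosome 16 (11141476 to 11146475) 3.29-fold (log2 1.72, SE 0.18), and a window within Peak1 on chromosome 9 (56221422 to 56226421) 2.09-fold (log2 1.06, SE 0.16). Of the regions that rose, one, at chromosome 16, 11144001 to 11144174, lies in Zc3h7a (4.38-fold, log2 2.13, SE 0.18, adjusted p 5.5e-06), and the other, at chromosome 3, 5860576 to 5860834, is 281980 bp from its nearest gene, Pex2 (6.35-fold, log2 2.67, SE 0.20, adjusted p 3.7e-06). Each was higher in G2 in 2 of 2 treatments.

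Windows that fell in G2 held the microRNA gene Mir470 (log2 -0.62), Amz2 (-0.80), and Iqca with 4930434B07Rik (-0.52). In all, limma called 2 regions higher and 0 lower (650 at an unadjusted p under 0.05, 550.5 by chance) and 4 windows higher and 3 lower (864, 766 by chance). With 1 Mb domain medians removed no region or window passed, but most loci higher in G2 kept their size: log2 2.36 for the Zc3h7a region, 1.77 for the Zc3h7a window, 2.16 for the chromosome 13 window and 1.10 for the Peak1 window. The region nearest Pex2 and the Rn18s-rs5 window lie in bins of 2 and 1 tested intervals, where the median removed holds the interval itself. Of the falls, Amz2 stood at -0.88 and Iqca at -0.49 with domain medians removed, and Mir470, the only tested window of its bin, at -0.03. As deposited (4 higher, 0 lower) the falls did not pass, at larger differences with larger SEs (Mir470 -0.74, SE 0.18; Amz2 -0.84, SE 0.21; Iqca -0.63, SE 0.18). The correction for reads hidden by the average left 3 higher and 1 lower. The windows that no longer passed there, Peak1 (1.295, SE 0.28, adjusted p 0.202), Mir470 (-1.36, SE 0.34) and Iqca (-1.23, SE 0.30), again had larger differences and larger SEs. With no filter Amz2 (-0.81) and Iqca (-0.52) did not pass (adjusted p 0.146 each). With a pseudocount of 2 and with median-of-ratios scaling, 2 windows passed as lower in each case.

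**Figure D4:**
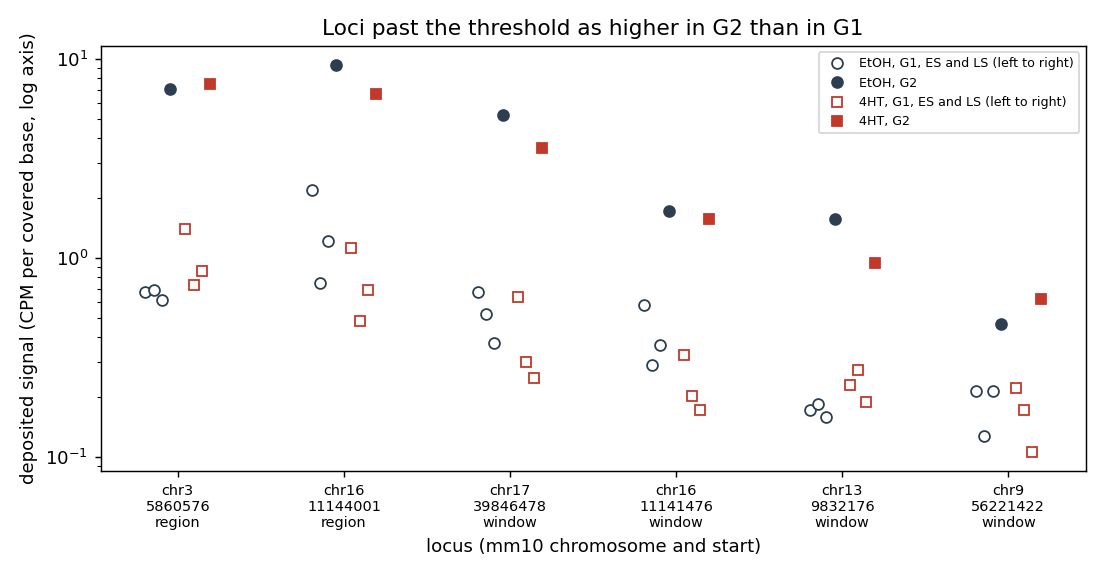
Deposited signal (CPM per covered base, log axis) at the 6 intervals past the threshold as higher in G2 than in G1. Circles are EtOH and squares 4HT, filled for G2; the G2 column lies above G1, ES and LS in both treatments at each locus, as at the chromosome 3 region with 7.47 in 4HT and 7.11 in EtOH against 1.41 and 0.672 in G1.

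Among the gene lists, G2 and mitosis passed camera as higher in G2 than in G1, and the call was lost with an estimated correlation (median log2 0.10, 20 of 27 windows above 0, camera adjusted p 0.0245; adjusted p = 0.692 with an estimated correlation, fry adjusted p = 0.0400). Its largest values were 0.30 for Kif20b, 0.29 for Aurkb, the kinase of the chromosomal passenger complex, and 0.27 each for Ccnb1 (cyclin B1) and Ttk. No mitotic member was called over all windows or adjusted over the list alone, where the FGF and MAPK feedback, neural crest and primitive endoderm lists had 1 each. None of the other lists passed camera. The estimated correlation of the G2 and mitosis list was -0.038, below the preset one. The loss of its call is therefore no evidence of correlation among its genes.

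In ES relative to G1, the lists of replication-dependent histones (lower) and of G2 and mitosis (higher) passed camera, and both calls were lost with an estimated correlation and with fry. The histone list had a median log2 of -0.12 with 7 of 36 windows above 0 (camera adjusted p 0.000573; adjusted p = 0.714 with an estimated correlation, fry adjusted p = 0.273). Its lowest members were H3c10 (-0.50), H2ac13 (-0.47), H2bc8 (-0.27) and H2ac8 (-0.26), of which H3c10 and H2ac13 share an overlapping pair of windows, as do H2bc8 and H2ac8. Of these windows 30 lie in the cluster on chromosome 13, 23 of them below 0, and 6 on chromosome 3, 6 of them below 0. The G2 and mitosis list had a median of 0.05 with 20 of 27 above 0 (camera adjusted p 0.0442; adjusted p = 0.714 with an estimated correlation, fry adjusted p = 0.0516), with 0.48 for Kif20b, 0.29 for Ccnf and 0.28 for Birc5. Adjusted over the list alone, 2 histone members were called and 1 each of the mitotic, p53 and primitive endoderm lists, and over all windows 0. The estimated correlation was 0.078 for the histone list, above the preset one, and -0.038 for G2 and mitosis, below it. The loss of the mitotic call is therefore no evidence of correlation among the mitotic genes.

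Single windows that fell in ES held Mir470 (log2 -0.73, SE 0.11), the 5S ribosomal RNA gene n-R5s138 (-0.75, SE 0.13) and Wwox (-0.77, SE 0.15). Mir470 stood at the 1-read value in ES of both treatments (0.103 in 4HT and 0.119 in EtOH), and n-R5s138 did so in 4HT. These ES values were set by the floor, so the sizes of the 2 falls and their agreement between treatments were not fully measured. As deposited 0 windows passed, at larger differences with larger SEs (Mir470 -0.79, SE 0.18; n-R5s138 -0.81, SE 0.19; Wwox -0.86, SE 0.21). With domain medians removed 0 passed as well, with n-R5s138 at -0.72 and Wwox at -0.68, and with Mir470, alone in its bin, at -0.07. With the higher coverage minimum, which leaves out Mir470 and n-R5s138, Wwox passed (-0.77). With no filter n-R5s138 (-0.75, adjusted p 0.0603) and Wwox (-0.77, adjusted p 0.184) did not pass, nor did Wwox without the G2 fraction (-0.77, adjusted p 0.123). None rose, with 1039 windows at an unadjusted p under 0.05 against 766 by chance. No region was called (785 at an unadjusted p under 0.05 against 550.5, smallest adjusted p 0.0624).

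LS differed from G1 at 11 windows, of which 3 rose and 8 fell. Those that rose held Tmem200c (log2 0.58), Gm10476 (0.62) and part of Soga3 (0.57). Those that fell held Mir470 (-0.71), n-R5s138 (-0.76), 2 overlapping windows at the vomeronasal receptor pseudogene Vmn2r-ps20 (-0.80 and -0.79), Dph6 (-0.64), Gm13246 (-0.64), part of Gm2237 (-0.63) and the Rn18s-rs5 window (-0.96, SE 0.19, adjusted p 0.0196). At the 1-read value stood Gm13246 in LS of both treatments, Mir470 in LS of EtOH and n-R5s138 in LS of 4HT. So did Tmem200c in G1 of EtOH and Gm10476 in G1 of 4HT, where the floor set the starting value. With the correction for reads hidden by the average the 8 falls passed and the rises did not, at larger differences with larger SEs (Tmem200c 1.35, SE 0.38; Gm10476 1.36, SE 0.33; Soga3 1.17, SE 0.27). With the higher coverage minimum, which leaves out all 3 rises, 4 windows passed as lower, the Rn18s-rs5 and both Vmn2r-ps20 windows among them. With no filter 2 passed as higher and 2 as lower. With a pseudocount of 0.5, with one of 2 and without the ES fraction, 2 passed as higher and 6 as lower in each case. With median-of-ratios scaling 2 passed as higher and 5 as lower. As deposited no window passed, with rises of 0.49 to 0.52 and falls of -0.69 to -0.89, all with larger SEs. With domain medians removed none passed either, with rises of 0.28 to 0.54, falls of -0.05 to -0.68 and 0.15 for the Rn18s-rs5 window, alone in its bin like Mir470 (-0.05). No region passed (802 at an unadjusted p under 0.05 against 550.5; 1058 windows against 766). No list passed camera, and the smallest p was that of G2 and mitosis (camera p 0.0130, adjusted p 0.247). Adjusted over the list alone, 1 apoptosis regulator was called.

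Differences between fractions were compared between the separate treatments. The r of 4HT and EtOH differences across regions was 0.0837 for ES (0.0650 to 0.103), 0.0837 for LS (0.0641 to 0.103) and 0.0442 for G2 (0.0229 to 0.0646), and across windows 0.0746, 0.0663 and 0.0621. For G2, Spearman's rho was 0.031 across regions and 0.036 across windows. The r values depend on the setting. Across the 92 regions with a mean signal of at least 1 they were 0.346 for ES, 0.221 for LS and 0.556 for G2. Those 92 include the 2 regions called in G2, with log2 differences of 2.28 and 3.06 (chromosome 3) and 2.40 and 1.86 (Zc3h7a) in 4HT and EtOH. Such values weigh heavily in r, and r without them was not computed. With no filter r across regions was 0.0214, 0.0260 and 0.0117. Across windows, those called included, G2 reached 0.199 with a pseudocount of 2. Whether these values differ from those between 4HT effects was not tested.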

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

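The higher coverage minimum, the correction for reads hidden by the average over covered bases and the omission of single fractions were chosen after seeing the data. The fry test was not part of the earlier design. The other settings were fixed before. Of 266 recomputed values of the 25 calls, in which an interval counts once for each comparison that called it, 175 kept direction and side of the threshold, 90 kept direction only and 1 reversed. Small changes were harder to detect in regions: in simulated data no fall and 11.8% of rises of log2 0.5 were recovered there, against 84.8% and 91.2% in TSS windows. The sizes of falls were understated in both tables. No paired analysis was possible because the columns carry no replicate number. For the same reason the omission of single replicates and the interaction were not run. Motif tests were not run, nor was a mean signal of at least 1 for TSS windows, which left fewer than 50. Unless stated, the cause of a shift was not tested.

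For 4HT against EtOH, the 2 TSS windows became 0 with a pseudocount of 2, with no filter, as deposited without centring, with 1 Mb domain medians removed and without the G2 fraction. They became 1 with the higher coverage minimum and without the G1 fraction, and 4 without the ES fraction, where the Gm21560 window no longer passed. The mean correlation of 4HT effects across regions was 0.0357 with a mean signal of at least 1 and 0.0232 with the higher coverage minimum; across windows it was -0.00546 with no filter.

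For ES against G1, the count of regions (0) became 2 with a mean signal of at least 1, 1 as deposited, 13 in a fit of the compared columns and 3 with the higher coverage minimum. The 3 windows became 0 as deposited and with domain medians removed, 11 in the fit of the compared columns and 1 with the higher coverage minimum. For LS against G1, the count of regions (0) became 2 with a mean signal of at least 1 and 21 in the fit of the compared columns, which has 1 residual degree of freedom. The 11 windows became 4 with no filter, 0 as deposited, 7 with median-of-ratios scaling, 0 with domain medians removed, 4 with the higher coverage minimum (0 higher), 8 with the read correction (0 higher), 7 without the G2 fraction and 8 without the ES fraction. For G2 against G1, the 2 regions became 0 with domain medians removed. There the Zc3h7a region kept a difference of 2.36 (SE 0.21, 2.13 and 0.18 before; adjusted p 0.231), while the region nearest Pex2, in a bin of 2, had 1.66 (SE 0.20, 2.67 and 0.20 before; adjusted p 0.680). The 7 windows became 4 as deposited (4 higher, 0 lower), 0 with domain medians removed (the chromosome 13 window at 2.16, Zc3h7a at 1.77 and Peak1 at 1.10 keeping their size), 15 in the fit of the compared columns (9 higher, 6 lower) and 4 with the read correction (3 higher, 1 lower). Removing a domain median takes a called interval out of its own bin when the bin holds few intervals, and 7 of the 25 calls lie in bins with fewer than 3. The Rn18s-rs5 window, lower in LS than in G1, reversed to 0.15 when domain medians were removed; it is the only tested interval of its bin.

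Across regions, the correlation of ES differences between treatments was 0.0214 with no filter, 0.346 with a mean signal of at least 1, 0.0583 with domain medians removed and 0.134 with the higher coverage minimum. The LS values under these settings were 0.0260, 0.221, 0.0579 and 0.136. For G2 they were 0.0117 with no filter, 0.0695 with the higher coverage minimum and 0.0905 with a pseudocount of 2. With a mean signal of at least 1 the G2 value was 0.556, across 92 regions that include the 2 called ones. Across windows, ES gave 0.0348 with no filter, 0.0418 with domain medians removed and 0.107 with the higher coverage minimum. LS gave 0.0227, 0.0208 and 0.103 under these settings and 0.0931 as deposited. G2 gave 0.105 and 0.199 with pseudocounts of 0.5 and 2, 0.0131 with no filter and 0.159 with the higher coverage minimum.

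The 2 gene lists of ES against G1 became 1 with pseudocounts of 0.5 and 2, with no filter, with the read correction and without the G2 fraction. They became 0 with domain medians removed, the higher coverage minimum, an estimated correlation and fry. The 1 list of G2 against G1 became 0 with domain medians removed, the higher coverage minimum and an estimated correlation.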

Other observations

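Of the tests in this part, only that of the shared G1 columns was written down before its result was seen, when the contrasts with G1 were already known.

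The windows with the highest mean signal overlapped predicted genes, the Rn18s-rs5 pseudogene or no gene. The window of the predicted genes Gm10222 and Gm10925 on chromosome 1 (24610351 to 24615350) had a level of 1990 times the 1-read value, and windows at the start of chromosome 9 reached 31.8. Over 23 tested windows at 5S ribosomal RNA genes, at the start of chromosome 9 and at loci on chromosomes 1 and 2, the G2 minus G1 difference had a median of 0.04 and ran from -0.39 to 0.52. At 677 regions with at least 5 times the 1-read value, where the floor has little weight, the deposited signal in LS exceeded that in G1 by a median log2 of 0.15 (0.10 to 0.19) in 4HT and 0.26 (0.22 to 0.30) in EtOH. In ES it was lower, by -0.21 (-0.25 to -0.17) and -0.06 (-0.10 to -0.02). The rise over G1 was not particular to LS: G2 stood at 0.05 (-0.01 to 0.10) in 4HT and 0.16 (0.14 to 0.20) in EtOH. The median log2 difference between 4HT and EtOH at these regions was 0.04 (-0.01 to 0.07) in G1, -0.08 (-0.12 to -0.03) in ES, -0.06 (-0.10 to -0.04) in LS and -0.06 (-0.10 to -0.03) in G2, with the intervals of ES, LS and G2 below 0. The limits in this paragraph measure the spread among regions within 1 pair of pooled columns, not among libraries. An effect of 4HT or of the fraction therefore cannot be told apart from a difference in enrichment between the libraries.

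The calls for 4HT were set against all 35 splits of the 8 columns into 4 and 4, in a fit without a fraction term. For regions the real split gave 0 calls, which all 35 splits reach by construction, so the count says nothing about chance; the highest other split gave 1. For TSS windows 12 splits gave at least the 1 call of the real split, and the highest other gave 4, in the split of G1 and ES from LS and G2, which follows the fractions. Only 8 of the 35 splits balance the fractions, and 3 of these 8, the real one included, gave at least 1 call, with 1 the highest of the others. Chance was not excluded for the windows by the 35 splits, and 8 splits are too few for a share under 0.05.

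The 6 intervals higher in G2 than in G1 were raised in both treatments. A depth floor was argued against, since the lowest ratio of deposited values was log2 1.13 where the 1-read values would give at most -0.17. The doubling of all DNA from G1 to G2 cancels in a signal scaled to library size and centred, so it would raise no single interval, Peak1 included. A doubling of copies at single loci, relative to the genome, was argued against as the whole cause at 5 of the intervals. Their lowest value was 1.72 (SE 0.18) against a bound of 1. Such a local doubling stays open for the Peak1 window at 1.06 (SE 0.16). All 6 intervals were selected for high values in these same columns, so the values set against both bounds may be overstated. The Zc3h7a region lies inside the Zc3h7a window, so these 2 intervals share reads and are 1 locus. For a rise of repeated sequence in general, the 23 windows above had a median of 0.0387, the highest at 0.52. Of these, 10 lie at 5S ribosomal RNA genes, at 1.32 to 1.90 times the 1-read value. None was chosen for the sequence of the Rn18s-rs5 window, and the sequence of the 6 intervals was not examined. The values cover only those 23 windows, so whether reads shared by repeats raised the 6 intervals stays open. Handling shared by the G2 columns cannot be told apart from the cell cycle phase, because each G2 column is the whole of its fraction, and no label names a batch; that all were raised in 2 of 2 G2 columns followed from their selection and decides nothing.

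In bins of 1 Mb, the LS minus G1 difference was lower where genes are dense: Spearman's rho was -0.127 in 4HT and -0.247 in EtOH over 816 bins of regions, and -0.0968 and -0.172 over 995 bins of windows, with the highest upper limit at -0.0299. Other contrasts with G1 leaned the same way in part, with intervals below 0 for G2 minus G1 in EtOH (-0.0738 in regions, -0.0694 in windows), for ES minus G1 in EtOH regions (-0.0915) and for 4HT minus EtOH in G1 regions (-0.0831). Without the G1 columns, LS minus ES and LS minus G2 gave 8 values from -0.227 to -0.0498, of which 7 had intervals below 0 and 1, LS minus ES in 4HT regions, reached 0.0255, so a part played by the shared G1 columns stays open. If ES is an earlier stage of replication than LS, copy number alone could give LS minus ES values below 0. Those values therefore cannot separate the shared G1 columns from copy number. LS minus G2, which also uses no G1 column, gave -0.130 and -0.219 in regions and -0.0876 and -0.101 in windows (4HT and EtOH). All 4 intervals lay below 0, with the highest upper limit at -0.0194. These 4 values argue against the shared G1 columns as the whole cause, while a part stays open. For LS minus G1, copy number of replicated DNA would give values of 0 or more, since gene-dense DNA replicates early, and the highest of the 4 was -0.0968. Lower enrichment in LS would lower strong regions, whereas these were higher by log2 0.26 in EtOH. A shift of signal toward gene-poor chromatin in LS may be involved, but this hypothesis was found and tested on the same columns, and other handling of the LS columns was not tested.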
